A study of Rattus norvegicus with 70 samples.

How the data were processed

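DNA methylation was measured by methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq), in which an antibody to methylated cytosine recovers methylated fragments and the read count of a genomic window follows the amount recovered there. The DNA came from adipocytes isolated by collagenase from the gonadal fat pads of F3 rats. Each of the 70 libraries was made from a pool of 2 to 5 animals, so a replicate is a pool and not an animal, and the spread between pools understates the spread between animals. The labels give lineage (atrazine, DDT or control), sex and phenotype (lean, normal or obese), which define 14 groups of 5 pools.

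Per the submitters' processing notes, the authors used FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR on genome build Rnor_6.0. Their versions, the aligner settings and any removal of duplicate reads are not given in the sources used here. The 8 deposited tables each hold a single phenotype comparison over 2782040 windows of 1000 bp. Per the file headers, each library has a raw read count per window, and these deposited counts were whole numbers with different totals between libraries. The deposited RPKM columns (reads per kilobase of window and per M reads, M for mega), calculated by the authors, were used only to check the counts. The authors' mean counts and mean RPKM per group equal the averages of those columns and were used for the same check. The deposited log2 fold changes, log2 abundances, p-values and adjusted p-values are the authors' edgeR output, given for windows with a summed count of at least 100 over the 10 libraries compared. The highest window count of a library lay between 1499 and 2073 whatever its total, so counts in the most covered windows have a ceiling.

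The counts of all 70 libraries were joined by window, with no library left over. Library totals ran from 7.03 to 66.98 M with a median of 39.72 M. Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package at version 1.17.8. The 17 mitochondrial windows were left out of every test, which leaves 2782023 nuclear windows. A window entered a test when its mean was at least 10 reads per library over the libraries compared. Counts were scaled by TMM (trimmed mean of M-values) on nuclear totals and tested with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all windows of a comparison and an adjusted p threshold of 0.05. At this depth the median tested window held 17.5 to 19.2 reads per library, and the median standard error of a log2 change was 0.269 to 0.309 across the 8 phenotype comparisons. Levels of single windows are given as CPM (window counts scaled to a library of 1 M counts), as mean ± SD over 5 pools.

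The 8 phenotype comparisons set the lean or obese pools against the normal pools of the same lineage and sex. Further comparisons set the normal pools of a treated lineage against the normal control pools of the same sex, tested the difference between 2 phenotype effects as an interaction term, and set females against males within the normal pools. The comparisons, their tests, the alternatives and the rule for naming regions were chosen before the data were examined, apart from the comparison of females with males, the library measures and the alternatives said below to be later. The rule was as follows. Windows past the threshold and within 1000 bp of each other were merged into a region, and the 10 regions higher and the 10 regions lower with the smallest p of their best window were named, unplaced scaffolds left out. Where fewer than 3 regions passed, the 3 windows with the smallest p are given as values that did not pass. A region's fold change and CPM are those of its best window.

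The test was tried on simulated data with changes of known size put into 50 windows per fold and comparison. Each comparison was drawn with a single dispersion for all its windows, without spread particular to a window or shared between pools. A 4-fold change was recovered in 82% to 100% of windows and a 2-fold change in 4% (lean against normal control females) to 56% (atrazine females). For each count of called windows, other splits of the same libraries into groups of the same sizes were tested on every 10th window. Where comparisons share control pools, the shared calls were set beside unchanged groups simulated around 1 mean per window and beside fits in which the control pools were divided between the comparisons. The replicate numbers do not pair the pools: window profiles of pools with the same number correlated between -0.45 and 0.391 after group means were removed.

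Each library was also described by its total, by the share of its counts on the X chromosome, the Y chromosome and the mitochondrial genome, by the share in the top 1% of autosomal windows, and by a component score. The score is the position of a library along the first principal component of log2 CPM (pseudocount 1) after removal of group means. It used 55229 autosomal windows, every 10th with a mean of at least 20 reads, and libraries of at least 10 M counts. The component was taken from libraries of the other sex, so a library never helps to define its own score. The component from males held 9.5% of the variance within groups of males, and that from females 18.9% within groups of females. Across windows these components correlated with r of 0.422, so females and males were scored on related but not identical axes. Group differences in these measures were tested with exact permutation tests, two-sided.

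Alternatives were RLE size factors, total counts without TMM, a minimum mean of 20 reads, no minimum, the replicate number as a block, DESeq2's Wald test, an unadjusted p under 1e-05 and the removal of each pool in turn. Added after seeing the data were the component score as a covariate, the top 1% share as a covariate, the log2 total count as a covariate, and the joint removal of a pair of control male pools. The gene annotation at hand is on a later rat assembly than the build of the windows, and it cannot be joined by position. Regions are therefore given by Rnor_6.0 coordinates alone, and gene names, promoters, gene lists and CpG content were not analysed here.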

Results

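Adipocyte DNA methylation was profiled in 1-year-old F3 rats whose F0 ancestors had been injected on days 8 to 14 of gestation with atrazine (a triazine herbicide), with DDT (an organochlorine insecticide) or with vehicle. Animals had been sorted as lean, normal or obese by adipocyte area, body mass index and abdominal fat. Pools of adipocyte DNA were available for lean and normal animals of the atrazine lineage, normal and obese animals of the DDT lineage, and lean, normal and obese animals of the control lineage, each in females and in males, with 5 pools per group. Total window counts per pool ran from 7.03 M (M for mega; DDT obese male 3) to 66.98 M (atrazine lean male 3). The groups overlapped in depth: atrazine normal females had 31.13 to 46.51 M, for example, and atrazine lean females 16.41 to 51.9 M. The pools carried the marks of their sex. The X chromosome took 4.37% to 4.54% of counts in the female groups and 3.04% to 3.32% in the male groups (group means, n = 5), and the Y chromosome took 0.062% to 0.0718% and 0.122% to 0.1343%. Control normal male 1 stood apart, with 3.98% on X and 0.088% on Y.

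**Figure D1:**
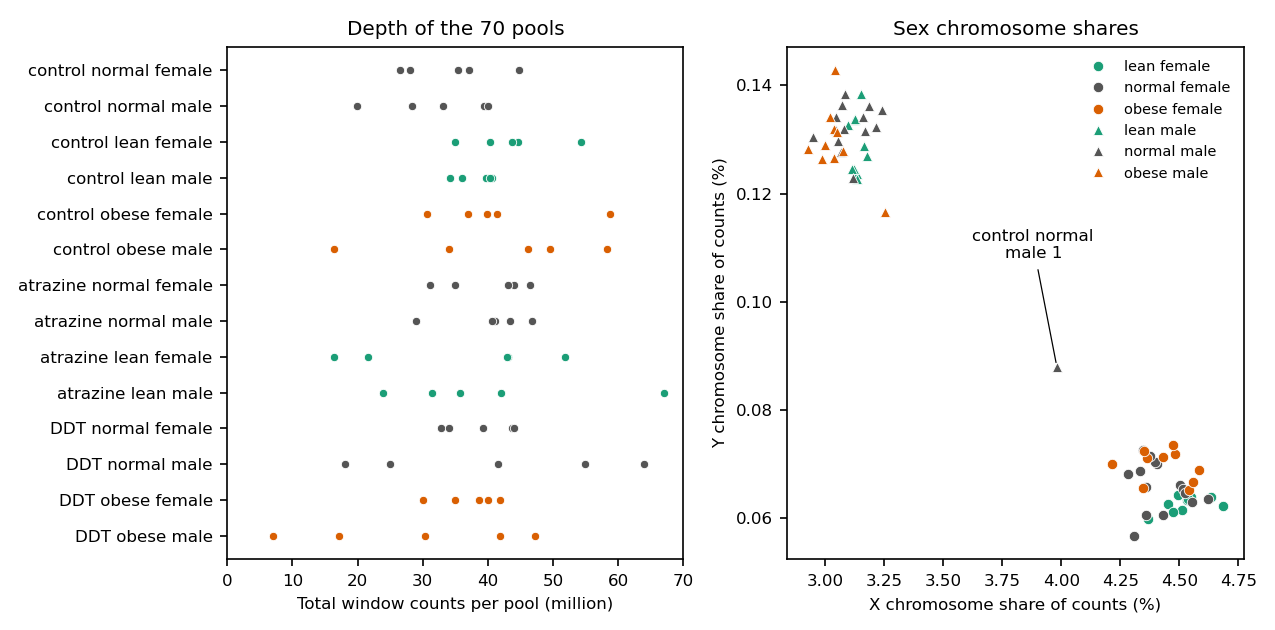
Left, total window counts of each pool (M) (1 point per pool, 5 per group), by group. Right, percent of counts on the X chromosome (horizontal) against percent on the Y chromosome (vertical) for each pool: females and males form separate clouds, and control normal male 1 (3.98% on X, 0.088% on Y) lies between them.

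Lean males of the atrazine lineage carried more immunoprecipitated DNA than their normal counterparts at many small regions. The leading region, chr6:106926001-106927000, had 3.11 ± 0.969 CPM in lean and 1.28 ± 0.24 CPM in normal pools (log2 change 1.28, SE 0.156, adjusted p = 4.07e-07, n = 5 each, 39 to 189 reads per pool), and every lean pool exceeded every normal pool. At chr2:242623001-242625000 the levels were 3.1 ± 1.17 and 1.25 ± 0.235 CPM (log2 change 1.30), and at chr8:23352001-23357000, a run of 5 windows, 1.96 ± 0.267 and 0.759 ± 0.249 CPM (log2 change 1.34). Fewer regions were lower in lean males. First among these was chr6:18599001-18600000, with 0.752 ± 0.169 CPM in lean and 1.63 ± 0.269 CPM in normal pools (log2 change -1.06, adjusted p = 0.000212), and the deepest fall among the named regions, -1.99, was at chr11:64914001-64915000, where levels were 0.115 ± 0.106 and 0.54 ± 0.178 CPM.

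The other named regions that were higher in lean atrazine males lay at chr2:67646001-67647000, chr15:105437001-105438000, chr12:24770001-24771000, chr2:18597001-18599000, chr10:15775001-15776000, chr8:17651001-17653000 and chr9:20437001-20438000, with log2 changes from 0.97 to 1.29. The other lower ones lay at chr14:95336001-95337000, chr4:104397001-104398000, chr1:60366001-60367000, chr15:55541001-55543000, chr20:48266001-48267000, chr14:96952001-96953000, chr14:17661001-17662000 and chr5:102417001-102418000, with log2 changes from -1.11 to -0.69. In this comparison of lean with normal atrazine males, 4286 of 1339641 tested windows passed the threshold, 3555 higher in lean (median log2 change 0.86) and 731 lower (median -0.80). They formed 4002 regions, of which 228 spanned more than 1 window. Of the windows higher in lean males, 2343 were among the 10% of windows with the highest coverage. Without atrazine lean male 5 the count was 657, and without atrazine normal male 1, 2 or 3 it was 1981, 1897 and 2221. DESeq2 called 1760 windows, and with the component score as a covariate 12 passed in the edgeR test (5 higher and 7 lower). With the top 1% share as a covariate 2456 passed.

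Between lean and normal females of the atrazine lineage, no window passed the threshold. The smallest p was at chr19:7929001-7930000, with 0.43 ± 0.207 CPM in lean and 1 ± 0.219 CPM in normal pools (log2 difference -1.13, SE 0.233, adjusted p = 1 by edgeR). Next came chr2:114916001-114917000, with 0.193 ± 0.0995 and 0.661 ± 0.305 CPM (log2 difference -1.54), and chr2:244097001-244098000, with 0.765 ± 0.223 and 1.36 ± 0.232 CPM (log2 difference -0.91). The former lies within chr2:114581001-114983000, an autosomal stretch that was higher in males than in females (see Other observations). By edgeR 0 of 1269732 windows passed and 60199 (4.74%) had an unadjusted p under 0.05, DESeq2 called 0, and the authors' table lists 0. Simulated changes of 2-fold were recovered in 56% of windows at the depth of these females and a single dispersion for all windows. Spread particular to a window or shared between pools was not simulated, so recovery in the data may be lower. Without atrazine normal female 5 the count was 1.

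Lean control females, whose ancestors received vehicle, carried less immunoprecipitated DNA than normal control females at most regions that differed. At chr4:114830001-114835000 the lean pools had 0.174 ± 0.0606 CPM and the normal pools 0.949 ± 0.402 CPM (log2 change -2.39, SE 0.334, adjusted p = 0.0383, n = 5 each, 4 to 48 reads per pool), and every lean pool was below every normal pool. The deepest fall among the named regions, -2.90, was at chr5:35369001-35370000, with 0.0723 ± 0.039 and 0.581 ± 0.37 CPM. Among the regions that were higher in lean, chr4:123729001-123730000 had 1.06 ± 0.212 CPM in lean and 0.389 ± 0.101 CPM in normal pools (log2 change 1.42), and chr16:56266001-56267000 had 0.453 ± 0.156 and 0.104 ± 0.0514 CPM (log2 change 2.10).

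The further regions lower in lean control females were chr13:112473001-112474000, chr5:149671001-149672000, chr2:34148001-34149000, chr19:48436001-48437000, chr13:4804001-4805000, chr13:112141001-112142000, chr17:45156001-45157000 and chr11:35871001-35872000, with log2 changes from -2.50 to -1.92. The further higher ones were chr5:107367001-107368000, chr12:14936001-14937000, chr5:170839001-170840000, chr9:75148001-75149000, chr8:124842001-124843000, chr11:24432001-24433000, chr1:80025001-80026000 and chr12:2225001-2226000, with log2 changes from 1.17 to 1.82. All 20 had an adjusted p of 0.0383, the smallest of the comparison. Of 1321191 windows tested between lean and normal control females, 13050 passed, 536 higher (median log2 change 1.19) and 12514 lower (median -1.47). The 12514 windows averaged 1.87 ± 0.852 CPM in normal and 0.714 ± 0.266 CPM in lean control females. Normal females of the atrazine and DDT lineages, at 0.795 ± 0.122 and 0.649 ± 0.0264 CPM, lay near the lean ones. The windows were picked as higher in normal than in lean control females, so the high level of the former follows in part from that choice. With all pools DESeq2 called 18268 windows, the authors' table lists 20138, and 177208 had an unadjusted p under 0.05 by edgeR. The edgeR count rested on single pools: it was 0 without control lean female 1, 2, 3 or 4 and without control normal female 2, 3, 4 or 5, 38059 without control lean female 5 and 133575 without control normal female 1. It was also 0 with a minimum mean of 20 reads, with total counts in place of TMM or with the log2 total count as a covariate, 4343 with the component score, 8276 with no minimum, 21085 with the top 1% share and 40713 with the replicate number as a block. Component scores of the 5 control normal females spread from -39.7 to 49.9.

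Obese control females likewise carried less immunoprecipitated DNA than normal control females at most regions that differed. At chr1:222968001-222969000 the obese pools had 0.287 ± 0.0671 CPM against 1.33 ± 0.517 CPM in normal pools (log2 change -2.21, SE 0.302, adjusted p = 0.0331, n = 5 each). The deepest fall among the named regions, -3.45, was at chr18:86402001-86403000, with 0.0521 ± 0.0315 and 0.6 ± 0.387 CPM. On the higher side, chr1:153051001-153052000 had 0.877 ± 0.129 CPM in obese and 0.334 ± 0.0855 CPM in normal pools (log2 change 1.37), and X:30299001-30300000, the only named region of this comparison on the X chromosome, had 0.675 ± 0.234 and 0.187 ± 0.109 CPM (log2 change 1.73).

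Also lower in obese control females were chr18:85508001-85509000, chr17:5088001-5089000, chr1:162408001-162409000, chr3:91780001-91781000, chr8:80441001-80443000, chr17:70478001-70479000, chr1:30725001-30726000 and chr3:72052001-72053000, with log2 changes from -2.56 to -1.74. Also higher were chr11:36410001-36411000, chr14:20119001-20120000, chr18:8698001-8699000, chr9:23768001-23769000, chr3:107230001-107231000, chr3:79399001-79400000, chr8:30445001-30446000 and chr7:30750001-30751000, with log2 changes from 1.21 to 1.95. Of 1301449 windows tested between obese and normal control females, 17699 passed, 614 higher (median log2 change 1.22) and 17085 lower (median -1.44), and all 20 named regions had an adjusted p of 0.0331. The 17085 windows, picked as higher in normal control females, averaged 1.67 ± 0.746 CPM in these and 0.643 ± 0.213 CPM in obese ones. Normal females of the atrazine and DDT lineages, at 0.759 ± 0.11 and 0.619 ± 0.0251 CPM, lay near the obese ones. With all pools DESeq2 called 22962 windows, the authors' table lists 28987, and 193168 had an unadjusted p under 0.05 by edgeR. The edgeR count was 0 without control normal female 2, 4 or 5 and without control obese female 2, 3 or 4, it was 1 without control normal female 3, and 146542 without control normal female 1. With the replicate number as a block or the log2 total count as a covariate it was 0, with the top 1% share 3431 and with total counts in place of TMM 5233.

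Obese control males showed the same balance, with most of the differing regions lower than in normal control males. The largest change was at chr14:17504001-17505000, where obese pools had 0.207 ± 0.0732 CPM and normal pools 3.96 ± 3.87 CPM (log2 change -4.23, SE 0.368, adjusted p = 7.64e-12, n = 5 each, 4 to 289 reads per pool). This window had pools below 0.3 and above 2.5 CPM within 5 of the 14 groups. The levels were 0.966 ± 0.297 and 3.19 ± 1.15 CPM at chr11:36160001-36161000 (log2 change -1.77, adjusted p = 1.8e-05) and 1.9 ± 0.305 and 5.24 ± 1.31 CPM at chr9:116856001-116857000, the smallest fall among the named regions (log2 change -1.46). On the higher side, chr7:77179001-77180000 had 2.03 ± 0.54 CPM in obese and 0.842 ± 0.194 CPM in normal pools (log2 change 1.22, adjusted p = 0.00137). At each of these regions every obese pool lay on the same side of every normal pool.

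The other regions lower in obese control males were chr1:98561001-98563000, chr9:80952001-80953000, chr8:63818001-63819000, chr2:241036001-241037000, chr16:43155001-43156000, chr3:77496001-77497000 and chr7:143246001-143248000, with log2 changes from -1.71 to -1.48. The other higher ones were chr11:11099001-11100000, chr11:59133001-59134000, chr1:95155001-95156000, chr2:60344001-60345000, chr2:235527001-235528000, chr3:3901001-3902000, chr4:113021001-113022000, chr1:38086001-38087000 and chr3:152754001-152755000, with log2 changes from 1.09 to 1.90. Of these, chr1:38086001-38087000 lies within chr1:38042001-38416000, an autosomal stretch higher in males than in females (see Other observations), and the normal pools include control normal male 1. Of 1270851 windows tested between obese and normal control males, 7134 passed, 279 higher (median log2 change 1.22) and 6855 lower (median -1.06), and 3697 of the lower windows were among the 10% with the highest coverage. The count was 4437 without control normal male 1, 2745 without control normal male 3, 1817 without control obese male 3, 3760 without control obese male 4 and 4732 without control obese male 5. It was 189 with the component score (149 higher and 40 lower), 2990 with no minimum, 12676 with the top 1% share, and 4208 without control normal male 1 and control obese male 1 together. After every library was thinned to the depth of the shallowest it was 2969, with the median change near its value (1.065 and 1.057).

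Between lean and normal control males no window passed the threshold. The smallest p was at chr3:117962001-117963000, with 0.878 ± 0.205 CPM in lean and 2.01 ± 0.718 CPM in normal pools (log2 difference -1.17, SE 0.207, adjusted p = 0.198 by edgeR). The next were chr15:28094001-28095000, with 1.31 ± 0.211 and 2.61 ± 0.802 CPM (log2 difference -0.997), and chr9:81378001-81379000, with 0.315 ± 0.0738 and 0.847 ± 0.317 CPM (log2 difference -1.48). By edgeR 0 of 1225881 windows passed and 73363 (5.98%) had an unadjusted p under 0.05, DESeq2 called 20, and the authors' table lists 0. The edgeR count was 83, 199 and 3 without control normal male 3, 4 and 5, 89 with the component score, 2 with the top 1% share, 2 with the log2 total count and 1 with the replicate number as a block.

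Obese males of the DDT lineage carried less immunoprecipitated DNA than normal DDT males at most regions that differed. The leading region, chr1:249695001-249696000, had 0.882 ± 0.27 CPM in obese and 2.86 ± 1.03 CPM in normal pools (log2 change -1.67, SE 0.192, adjusted p = 4.22e-09, n = 5 each, 4 to 219 reads per pool). At chr2:11316001-11317000 the levels were 1.95 ± 0.367 and 4.27 ± 0.572 CPM (log2 change -1.18), and at chr1:255732001-255733000 they were 2.24 ± 0.717 and 5.09 ± 0.575 CPM (log2 change -1.14). Among the regions higher in obese males, chr5:77669001-77671000 had 2.84 ± 0.656 and 1.39 ± 0.767 CPM (log2 change 1.23, adjusted p = 8.84e-05; its window chr5:77669001-77670000 had pools below 0.3 and above 2.5 CPM within 5 of the 14 groups), and a second region further on, chr5:77694001-77697000, had 3.33 ± 1.01 and 1.84 ± 0.725 CPM (log2 change 0.86). The window at chr14:17504001-17505000, which fell in obese control males, was higher in obese DDT males, with 4.33 ± 1.51 and 2.32 ± 1.49 CPM (log2 change 0.94, adjusted p = 0.0068).

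The other regions lower in obese DDT males were chr8:12103001-12104000, chr14:28803001-28804000, chr4:52710001-52711000, chr11:87271001-87272000, chr11:69043001-69044000, chr11:69202001-69203000 and chr1:6122001-6123000, with log2 changes from -1.36 to -1.03. The other higher ones were chr19:34225001-34226000, chr14:4295001-4296000, chr3:90855001-90856000, chr1:181772001-181773000, chr18:36227001-36228000, chr3:63633001-63634000 and chr7:63735001-63736000, with log2 changes from 0.81 to 1.99. Of 1186502 windows tested between obese and normal DDT males, 2434 passed, 142 higher (median log2 change 1.02) and 2292 lower (median -0.85), and 1599 of the lower windows were among the 10% with the highest coverage. The count was 607 and 358 without DDT normal male 1 and 2, and 313 and 189 without DDT obese male 1 and 2. It was 0 in edgeR with the component score as a covariate, against 1734 by DESeq2, 1670 in the authors' table and 93193 windows with an unadjusted p under 0.05, and it was 3953 with a minimum mean of 20 reads and 1486 with none. After every library was thinned to the depth of the shallowest it was 12, with the median change near its value (0.855 and 0.859) and fewer reads to test.

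Between obese and normal females of the DDT lineage 1 window passed. This was chr3:64210001-64211000, with 6.59 ± 1.44 CPM in obese and 3.47 ± 0.512 CPM in normal pools (log2 change 0.91, SE 0.108, adjusted p = 9.7e-09, n = 5 each, 102 to 278 reads per pool), and every obese pool exceeded every normal pool. The next windows did not pass. They were chr4:60118001-60119000, with 2.87 ± 0.807 and 1.69 ± 0.319 CPM (log2 difference 0.75, adjusted p = 0.149), and chr14:46526001-46527000, with 12.1 ± 4.4 and 8.22 ± 1.61 CPM (log2 difference 0.55). Of 1278386 windows, 70104 (5.48%) had an unadjusted p under 0.05, DESeq2 called 1 and the authors' table lists 3. The edgeR count was 135 without DDT obese female 1, 8 without DDT obese female 5 and 4 without DDT normal female 3.

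**Figure D2:**
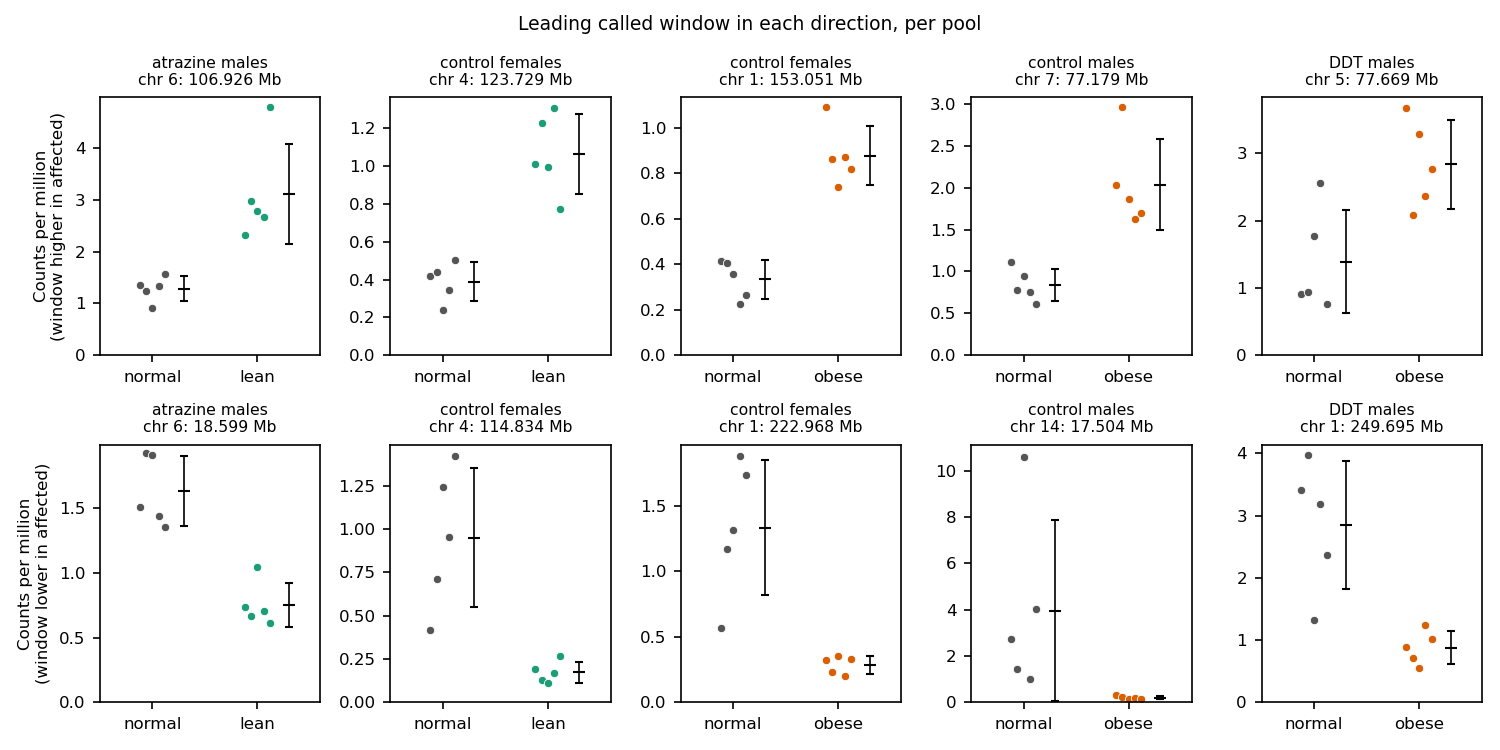
CPM of each pool (points, 5 per group) with the mean and SD (bars) at the leading region in each direction for 5 phenotype comparisons. At chr6:106926001-106927000 the lean atrazine males average 3.11 CPM against 1.28 CPM in normal ones, and at chr14:17504001-17505000 the normal control males spread widely around 3.96 CPM (SD 3.87).

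Some of the comparisons with no pool in common had windows that fell in both. Of the windows lower in lean control females, 2910 were also lower in obese control males, where 67.7 would be shared by independent calls, and of those lower in obese control males, 1263 were also lower in obese DDT males, against 13.7. Lower calls pile up at high coverage: in lean control females 5848 of 12514 were among the 10% of windows with the highest coverage. The numbers for independent calls, here and below, make no allowance for that and are too low for it. Obese DDT females did not share this: the windows lower in obese control males had a median log2 difference of 0.05 there, 59.9% of them higher, and none passed by edgeR. Lean atrazine males went the other way: 1573 of the windows higher there were lower in obese control males, and 856 were lower in obese DDT males. A set of 471 windows was lower in lean control females, obese control females, obese control males and obese DDT males, and 190 of these were higher in lean atrazine males. At chr20:2392001-2393000, 1 of the 190, the log2 changes were 1.06 in lean atrazine males and -1.88, -2.01, -1.68 and -1.24 in those comparisons. The calls of lean and of obese control females fell to 0 without single pools, so the 2910, 471 and 190 windows that need them rest on those pools too. The 3555 windows higher in lean atrazine males averaged 2.21 ± 0.765 CPM there, 1.26 ± 0.178 CPM in normal atrazine males, 3.05 ± 0.862 CPM in normal control males and 4.22 ± 2.01 CPM in normal control females. Normal atrazine males were the lowest of the 14 groups, and the groups not named here ran from 1.59 (normal DDT females) to 2.82 CPM (normal DDT males).

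The lean and obese control females were both set against the same 5 normal pools, which makes their changes alike by construction. Over all windows 6945 were lower in both, against 172 for independent calls. On every 10th window 672 were lower in both, against 16.2, the log2 changes correlated across windows with r of 0.767, and their covariance was 0.154. Unchanged groups simulated with shared controls gave r of 0.535 and a covariance of 0.0544. With the control pools divided between the comparisons r was 0.096 and 0.197 and the covariances 0.0246 and 0.0477, and in each division 1 of the comparisons had no lower window, so that none could be shared. Windows, as neighbours on 1 genome measured in the same pools, are not independent replicates. In control males the corresponding r was 0.563 with a covariance of 0.0614, against 0.531 and 0.048 simulated, and the divided controls gave r of 0.033 and 0.001 with 20 windows lower in both (0.194 if independent) in the first and 0 in the second, where 7 were lower in lean males.

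The difference between phenotype effects was itself tested. In males the effect of leanness in the atrazine lineage differed from that in the control lineage at 7560 windows, 7226 of them in the positive direction, led by chr2:242623001-242625000 (log2 difference 1.89, adjusted p = 4.85e-06) and chr2:18597001-18599000 (1.85). Without atrazine lean male 5 the count was 2797. In females the same test gave 1 window, chr6:61779001-61780000 (log2 difference 2.77, adjusted p = 0.0489). Without control normal female 3 the count was 1, without control normal female 1 it was 49989, without control lean female 5 it was 8796, and without any other single pool it was 0 by edgeR, where 118106 windows had an unadjusted p under 0.05 with all pools. It was 0 with RLE size factors and 170 with the replicate number as a block.

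For obesity, the DDT and control effects in males differed at 4 windows. They were chr14:17504001-17505000 (log2 difference 5.15, SE 0.463, adjusted p = 5.89e-14), chr11:82209001-82210000 (3.85), chr20:34771001-34772000 (1.96) and chr5:77669001-77670000 (3.23). The windows on chromosomes 14 and 5 each had pools below 0.3 and above 2.5 CPM within 5 of the 14 groups, so they vary widely between pools of the same group. The count was 8 without control obese male 1. In females by edgeR 0 windows passed and 139164 (10.78%) had an unadjusted p under 0.05, and the count was 75062 without control normal female 1, 13977 without control obese female 1 and 10452 without control obese female 5.

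Between the sexes, the effect of leanness in the atrazine lineage differed at 2020 windows, 1917 of them in the negative direction, led by chr12:24770001-24771000 (log2 difference -1.73, adjusted p = 3.75e-05). That count was 221 without atrazine lean male 5, 1085 and 1199 without atrazine lean female 1 and 3, 963 and 811 without atrazine normal female 2 and 3, and 995, 996 and 1282 without atrazine normal male 1, 2 and 3. The effect of obesity in the DDT lineage differed between the sexes at 272 windows, 263 of them in the positive direction (females minus males), led by chr20:2063001-2064000 (1.85, adjusted p = 0.000914) and including chr1:249695001-249696000 (1.72). That second count was 163, 113, 151 and 125 without DDT normal female 1, 2, 4 and 5, and 96, 49, 620 and 429 without DDT normal male 1, 2, 3 and 5. It was 93, 34 and 693 without DDT obese female 1, 3 and 5, and 64, 16, 838 and 422 without DDT obese male 1, 2, 4 and 5. In the control lineage no window differed between the sexes by edgeR: 0 passed for leanness (84732 with an unadjusted p under 0.05) and 0 for obesity (60887). Without control normal female 1, lean female 5, normal female 5 or normal male 3 the leanness count was 14683, 5, 1 and 1, and without normal female 1, normal female 4 or obese male 5 the obesity count was 4, 1 and 1.

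**Figure D3:**
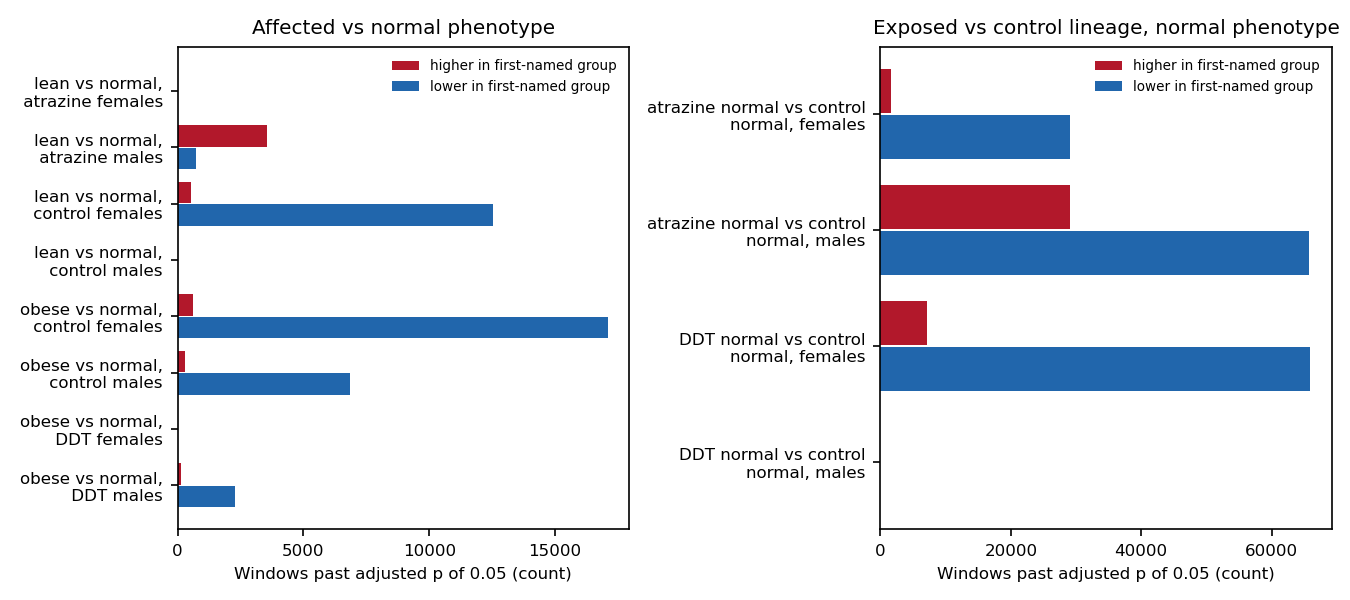
Number of windows past an adjusted p of 0.05 (edgeR) that were higher or lower in the first-named group, for the 8 phenotype comparisons (left) and for normal pools of the treated lineages against normal control pools (right). Each comparison has 5 pools per group, and bars start at 0.

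Comparing lineages asks whether ancestral exposure left a difference among animals of normal phenotype. The lineages may have been handled in separate batches, which the labels do not give, so a batch and ancestral exposure cannot be told apart here. Normal males of the atrazine lineage differed widely from normal control males. At X:32496001-32499000 they had 1.46 ± 0.533 CPM against 6.36 ± 2.28 CPM (log2 change -2.15, adjusted p = 6.31e-12, n = 5 each), and at chr3:166220001-166222000 1.42 ± 0.356 against 5.73 ± 1.79 CPM (log2 change -2.02). In the other direction, chr18:26177001-26183000 had 2.69 ± 0.427 against 0.987 ± 0.267 CPM (log2 change 1.48, adjusted p = 5.07e-08). Of 1239606 windows 94713 passed, 29025 higher and 65688 lower in atrazine males, and the longest region held 36 windows. The count was 63075 without atrazine normal male 1, 60417 without control normal male 1, 54984 with the log2 total count as a covariate, and 11672 with the component score, of which 8703 were higher and 2969 lower.

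Normal females of both treated lineages were lower than normal control females at most differing regions. In atrazine females, chr8:15595001-15598000 had 0.636 ± 0.154 CPM against 4.68 ± 2.94 CPM in control females (log2 change -2.87, adjusted p = 0.00143), and chr9:104569001-104572000 had 1.49 ± 0.342 against 0.55 ± 0.212 CPM (log2 change 1.43). The former lies within chr8:15531001-15694000, an autosomal stretch that was higher in males than in females (see Other observations). In DDT females, chr3:82596001-82597000 had 0.485 ± 0.123 against 3.36 ± 1.83 CPM (log2 change -2.78, adjusted p = 0.000425), and chr8:52243001-52247000 had 1.75 ± 0.367 against 0.614 ± 0.159 CPM (log2 change 1.51). The window chr2:231815001-231816000 was lower in both, with log2 changes of -2.63 in atrazine and -2.76 in DDT females. Of 1248870 windows 30765 passed in atrazine females (1612 higher, 29153 lower), and of 1247913 windows 73163 passed in DDT females (7187 higher, 65976 lower). The atrazine count was 5564, 16600, 20367, 4207 and 3854 without atrazine normal female 1 to 5 in turn, 146381, 10254, 2969 and 3756 without control normal female 1, 3, 4 and 5, 14181 with the replicate number as a block, and 12 with the log2 total count as a covariate. The DDT count was 215493, 40529 and 37875 without control normal female 1, 4 and 5, 44703 with the component score, and 21341 with the log2 total count.

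These lineage comparisons share the normal control pools. On every 10th window 2567 were lower in both female lineages, against 136 for independent calls, with r of 0.808 (0.532 simulated) and a covariance of 0.1761 (0.0503 simulated). With the control pools divided r was 0.129 and 0.318 and the covariances 0.0355 and 0.0798, and too few windows were lower in 1 of the comparisons (0 and 3) for a count of shared ones. In males r was 0.638 with a covariance of 0.0994, against 0.533 and 0.0454 simulated, and the divided controls gave r of 0.187 and 0.227 and covariances of 0.0407 and 0.0515. The first division left no lower window in DDT males, and the second gave 35 windows lower in both (6.72 if independent).

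Normal males of the DDT lineage differed from normal control males at 4 windows. They were higher at chr19:50419001-50420000, with 1.87 ± 1.06 against 0.446 ± 0.217 CPM (log2 change 1.94, adjusted p = 0.00059), and at chr8:52244001-52245000, with 1.81 ± 0.315 against 0.718 ± 0.358 CPM (log2 change 1.31, adjusted p = 0.0339). They were lower at X:88080001-88081000, with 0.198 ± 0.0621 against 0.761 ± 0.226 CPM (log2 change -1.81), and at chr14:22531001-22532000, with 0.189 ± 0.1 against 0.632 ± 0.31 CPM (log2 change -2.04). Of 1250934 windows 97149 (7.77%) had an unadjusted p under 0.05. The edgeR count was 1 without DDT normal male 1, 2, 3 or 5 or control normal male 2, it was 2 without DDT normal male 4 or control normal male 1 or 4, it was 0 without control normal male 5 and 1199 without control normal male 3, and it was 1088 with the component score and 1 with a minimum mean of 20 reads, with the log2 total count as a covariate or with the replicate number as a block.

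The library measures were compared between the groups of each phenotype comparison by exact permutation tests, where 5 against 5 pools cannot give a p below 0.00794. Over 8 comparisons this adjusts to 0.0635, so a measure that differed in 1 comparison only could not pass 0.05. In these permutation tests the smallest adjusted p was 0.0635, for the X share (p = 0.00794) and the component score (p = 0.0238) in atrazine males, and for the component score in obese against normal control males and DDT males (p = 0.0159 each). Mean component scores were -10.5 in lean and -31.3 in normal atrazine males. They were -11.3 in obese and 28.3 in normal control males, and -7.3 in obese and 17.2 in normal DDT males.

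Against the authors' own results, the log2 changes correlated across windows with r of 0.988 to 1. The authors' tables list 2576 windows past an adjusted p of 0.05 for lean atrazine males, 20138 for lean control females, 28987 for obese control females, 6974 for obese control males and 1670 for obese DDT males. The higher and lower windows among them were 1656 and 920, 2212 and 17926, 2531 and 26456, 649 and 6325, and 187 and 1483 in the same order, so that lean atrazine males had fewer higher and more lower windows than in the tests above, and control females more higher ones. Of the listed windows, 1809, 12943, 17626, 5382 and 1273 passed in the tests above, all in the same direction.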

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

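The tests of an X chromosome change alone and of low depth in control normal male 1, and the fits with depth, the component score and the top 1% share as covariates, were chosen only after the result they concern had been seen.

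A pool was picked out when it lay far from the other 4 of its group, by a gap test (Dixon's) that chance passes in about 1 in 20 groups. Among the library measures this happened in 9 of 84 groups, where chance gives 4.2, and among the named windows in 23 of 218, where chance gives 10.9. The X share was 4.623% in control normal female 1 (others 4.284% to 4.358%) and 3.981% in control normal male 1 (others 3.079% to 3.238%). The Y share was 0.088% in control normal male 1 (others 0.1229% to 0.1355%) and 0.1166% in control obese male 1 (others 0.1263% to 0.129%). The mitochondrial share was 0.0371% in atrazine normal female 3 (others 0.046% to 0.0492%) and 0.0911% in control obese male 2 (others 0.0423% to 0.0542%). The component score was 19.89 in control lean male 1 (others 1.48 to 5.16), 80.79 in control normal male 3 (others 1.87 to 22.23) and -11.32 in DDT obese female 1 (others 9.62 to 12.84).

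Atrazine lean male 5 lay above the other lean atrazine males at 7 of the named regions that were higher in lean. It had 4.79 CPM at chr6:106926001-106927000 (others 2.33 to 2.99), 5.18 at chr2:242623001-242624000 (2.45 to 2.81), 8.82 at chr2:67646001-67647000 (4.23 to 5.09), 4.15 at chr12:24770001-24771000 (1.91 to 2.4), 6.4 at chr2:18598001-18599000 (2.44 to 3.41), 7.59 at chr10:15775001-15776000 (3.77 to 4.09) and 10.7 at chr9:20437001-20438000 (5.29 to 6.56). In the same comparison atrazine normal male 2 had 1.87 CPM at chr10:15775001-15776000 (others 2.29 to 2.38) and atrazine lean male 3 had 1.04 CPM at chr6:18599001-18600000 (0.611 to 0.734). Atrazine normal female 3 had 1.77 CPM at chr2:244097001-244098000 (1.2 to 1.33).

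Among control females, control normal female 1 had 0.815 CPM at chr5:170839001-170840000 (others 0.267 to 0.416), 0.397 at chr2:34148001-34149000 (1.29 to 1.48) and 0.46 at chr8:30445001-30446000 (0.163 to 0.226). Control normal female 5 had 1.22 CPM at chr5:35369001-35370000 (0.309 to 0.533) and control normal female 4 had 1.02 at chr3:72052001-72053000 (0.44 to 0.597). Control lean female 4 had 0.678 CPM at chr12:2225001-2226000 (0.411 to 0.47), control lean female 5 had 0.463 at chr13:4804001-4805000 (0.166 to 0.248), and control obese female 1 had 0.569 at chr18:85508001-85509000 (0.129 to 0.209). Among males, control obese male 3 had 0.434 CPM at chr2:60344001-60345000 (0.739 to 0.835) and control normal male 3 had 3.73 at chr3:77496001-77497000 (1.45 to 2.06). DDT obese male 3 had 1.1 CPM at chr3:90855001-90856000 (0.36 to 0.547) and 1.37 at chr3:63633001-63634000 (0.78 to 0.949), and DDT normal male 4 had 0.342 at chr3:90855001-90856000 (0.0403 to 0.126).

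Differences between effects that passed their own test were those of leanness between atrazine and control males (7560 windows, 2797 to 9691 when 1 pool was left out, lowest without atrazine lean male 5) and females (1 window), and of obesity between DDT and control males (4 windows, 8 without control obese male 1). Between females and males the effect of leanness in the atrazine lineage differed at 2020 windows (221 without atrazine lean male 5) and that of obesity in the DDT lineage at 272 windows (16 without DDT obese male 2). Of these 5, only leanness between atrazine and control males had a count that no other split of the pools reached on the windows sampled. Chance is not excluded for the others. The single window in females passed with an adjusted p of 0.0489, and 49989 windows passed without control normal female 1.

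Windows called in the same direction in comparisons with no pool in common were many more than independent calls give, as with 1263 windows lower in both obese control males and obese DDT males against 13.7. That 13.7 makes no allowance for calls being more frequent at high coverage. A difference in depth was argued against in males, where log2 total count as a covariate left at least 0.99 of the median change of called windows and at least 3022 calls. A difference in the top 1% share was argued against in males too, where at least 0.86 of the median change was left with that share as a covariate. In control females 0.7 (lean) and 0.6 (obese) was left with it, so a part that goes with the top 1% share stays open there. In control females 20254 and 25150 windows still passed in lean and obese ones after thinning to equal depth, so the calls do not need unequal read numbers. Thinning leaves the expected change as it was, so it cannot test what else goes with depth. What goes with depth in control females cannot be told apart from phenotype: with log2 total count as a covariate the median change fell from 1.458 to 0.897 (0.62 of it) in lean and from 1.429 to 1.113 in obese ones, the median SE rose from 0.335 to 0.396 and 0.370, and 0 windows passed by edgeR. Across 4234 windows called in lean atrazine males, the lean effects of atrazine and control males correlated with r of -0.491, and 13.3% had the same sign. These windows thus showed no lean change common to both lineages. The mean component score, though, differed between lean and normal pools by 20.9 in atrazine and by -21.1 in control males, which alone would oppose the signs. Across all windows tested in both, r was -0.082, so a shared lean effect beneath that component stays open. With the component score, which is defined on the other sex and within groups, as a covariate, the median change fell from 0.849 to 0.404 in atrazine males and from 0.855 to 0.356 in DDT males, and in no comparison did more than 0.66 of it remain. In atrazine males and DDT males 12 and 0 calls remained, but the median SE of the called windows also rose, from 0.182 to 0.218 and from 0.186 to 0.315, and whether the smaller changes alone would have ended the calls was not tested. Part of these changes may belong to a component along which pools vary within groups too, and whether that component is technical or a state of the fat pad cannot be told apart, since the labels give no batch.

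In control normal male 1 both sex chromosomes lay between the male and female pools. If the pool held DNA of female animals, windows that differ between the sexes in both treated lineages would all give 1 female share, and the estimates were 0.388 from X windows, 0.609 from Y windows, and 0.368 and 0.459 from autosomal windows higher in females and in males. The highest values in the other control male pools were 0.134, 0.414, 0.142 and 0.167, the 0.414 in control obese male 1, whose X estimate was -0.064. An X chromosome change alone is argued against by the Y estimate of 0.609 and the autosomal ones, and low depth by the pool's total of 39.47 M, within the range of its group. DNA of female animals may be present, as all 4 estimates exceed those of the other pools. The Y estimate differs from the X estimate by more than the limit set for a single share. Y estimates of the other control male pools themselves ran from -0.337 to 0.414, so that gap cannot count against female DNA. The explanation stays open, and the count for obese control males was 4437 without the pool.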

How the results depend on the processing

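The component score, the top 1% share and the depth (log2 total count) as covariates, the thinning of libraries and the joint removal of control normal male 1 and control obese male 1 were chosen after seeing the data. No named window reversed its direction in the alternatives tested window by window, and counts not given below stayed within 1.5 times the reported one. Unless a reason is given, the cause was not tested.

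With DESeq2 1760 windows passed in atrazine males and 20 in lean control males. RLE size factors gave 0 for the leanness difference between atrazine and control females in edgeR, where 118106 had an unadjusted p under 0.05 and 1 had passed. Total counts without TMM gave 0 in lean and 5233 in obese control females. A minimum mean of 20 reads gave 0 in lean control females, 3953 in DDT males and 1 in DDT against control males, and no minimum gave 2723 in atrazine males, 8276 in lean control females, 2990 in obese control males and 1486 in DDT males. The replicate number as a block gave 40713 in lean control females, 1 in lean control males, 0 in obese control females, 14181 in atrazine against control females, 1 in DDT against control males and 170 for the leanness difference in females. An unadjusted p under 1e-05 gave 6 in atrazine females, 1624 in atrazine males, 253 and 39 in lean control females and males, 351 and 1980 in obese control females and males, and 20 and 866 in DDT females and males, a stricter limit by construction wherever the adjusted one had passed more.

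The component score gave 12 in atrazine males, 4343 and 89 in lean control females and males, 189 in obese control males, 0 in DDT males, 11672 in atrazine against control males (8703 higher, 2969 lower), and 44703 and 1088 in DDT against control females and males. The balance between directions turned in 3 of these: in atrazine males from 3555 higher and 731 lower to 5 and 7, in obese control males from 279 and 6855 to 149 and 40, and in atrazine against control males from 29025 and 65688. Depth as a covariate gave 0 in lean and in obese control females by edgeR, 2 in lean control males, 12 and 54984 in atrazine against control females and males, and 21341 and 1 in DDT against control females and males. Thinning every library to the shallowest of its comparison, tried in the 5 comparisons with many calls, gave 20254 in lean control females, 2969 in obese control males and 12 in DDT males, where the median change of the windows called before stayed near its value by construction (1.458 and 1.470, 1.065 and 1.057, 0.855 and 0.859). The top 1% share gave 2456 in atrazine males, 21085 and 2 in lean control females and males, and 3431 and 12676 in obese control females and males. Without control normal male 1 and control obese male 1 together, obese control males had 4208.

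With 1 pool left out at a time, which leaves fewer samples, the counts ran from 0 to 1 in atrazine females, 657 to 5010 in atrazine males, 0 to 133575 and 0 to 199 in lean control females and males, 0 to 146542 and 1817 to 9221 in obese control females and males, and 1 to 135 and 189 to 3630 in DDT females and males. They ran from 2969 to 146381 and 60417 to 115504 in atrazine against control females and males, and from 37875 to 215493 and 0 to 1199 in DDT against control females and males. For the leanness difference between lineages the range was 0 to 49989 in females and 2797 to 9691 in males, and for the obesity difference 0 to 75062 in females and 3 to 8 in males. Between the sexes it was 221 to 2961 and 0 to 14683 for leanness in the atrazine and control lineages, and 0 to 4 and 16 to 838 for obesity in the control and DDT lineages. In each result that uses the control normal females, the largest value came without control normal female 1.

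Of the named regions, 20 of 20 in atrazine males, 19 of 20 in obese control males and 12 of 20 in DDT males stayed past the threshold without any 1 pool, and 0 of 20 in lean and in obese control females. Over the 8 phenotype comparisons 55 named windows kept their side of the threshold with the component score and 54 fell short of it. All 109 kept it with RLE size factors and with no minimum. With the log2 total count as a covariate 68 kept it and 40 fell short. With the replicate number as a block, and likewise with total counts without TMM, 89 kept it and 20 fell short. With a minimum mean of 20 reads 75 kept it and 14 fell short. A simulated 2-fold change was recovered in 4% of windows in lean control females, where the dispersion was 0.0823, and in 56% in atrazine females, where it was 0.0113.

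Planned but not run, for lack of an annotation or CpG counts on the build of the windows, were the CpG enrichment covariate, alone and with the replicate block, the CpG enrichment comparisons, the promoter and gene-body tests and the gene lists with their correlation settings.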

Other observations

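The sex differences and the levels of a window on chromosome 14 were described only after they had been seen, while the tests of the autosomal stretches and the splits were chosen before their results.

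Females and males of normal phenotype differed on the X chromosome in both treated lineages. In the control lineage, whose normal male pools include control normal male 1, 3497 windows over all chromosomes differed by edgeR, 1234 higher and 2263 lower in females. These control calls were not used below. The median log2 difference of X windows, females over males, was 0.67 in atrazine and 0.51 in DDT animals, and 3983 X windows were higher in females in both, against 2480 for independent calls. At X:15099001-15100000 the log2 difference was 5.07 in atrazine and 5.27 in DDT animals, and 307 X windows exceeded 2 in both. The X chromosome was not uniform: 499 windows were higher in males in both lineages, such as X:55001-56000 with -5.20 and -4.30. Y windows had median differences of -0.44 and -0.40, and 188 were higher in males in both. Over X windows the differences of the lineages correlated with r of 0.649 and over autosomal windows with r of -0.008. Neighbouring windows are not independent replicates.

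On the autosomes 151 windows were higher in females and 3105 higher in males in both lineages (29.3 and 150 if independent), while 5144 were called in opposite directions. Runs of calls in atrazine animals, whether or not called in DDT animals, marked 33 stretches. Of these, 5 were higher in females, covering 546 kb, and 28 higher in males, covering 8884 kb. The stretches held 2632 of the autosomal windows called in both lineages, so the shared calls were clustered. The stretch at chr7:21243001-21981000 had median log2 differences of -3.43 in atrazine and -2.52 in DDT animals, and chr1:146959001-147096000 had 0.85 and 0.75. The window chr17:36772001-36773000 was higher in females by 4.81 and 3.62 on the log2 scale, and the adjacent chr17:36771001-36772000 by 3.71 and 2.78.

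Chance in 1 set of libraries is argued against as the source of the stretches, since 100% of those defined in atrazine animals kept their direction in DDT animals. Sequence of the X or Y chromosome placed on an autosome in the genome build is a candidate explanation: at least 72% of stretch windows of either direction were shifted that way in DDT animals, and the stretches higher in females had a median of 0.69, near the X median of 0.51. The stretches higher in males had a median of -2.20 against -0.40 for Y windows, which is stronger than the Y chromosome of the build itself, so a misplaced Y sequence and a sex difference in methylation cannot be told apart from these windows. Methylation that differs between the sexes was not tested, as the reads carry no base-level values here.

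The window chr14:17504001-17505000 behaved unlike its surroundings. Over the 69 pools with at least 10 M counts it ran from 0.0242 to 10.2 CPM, with 17 pools below 0.3 CPM and 37 above 2.5 CPM, and both levels occurred within 5 of the 14 groups, while the flanking windows averaged 0.206 to 0.708 CPM per pool. Of 87 autosomal windows with both levels among the pools, only this one and chr5:77669001-77670000 had them in at least 3 groups (5 each, with 39.2% and 33.2% of the variance between groups), but the 87 mostly set whole groups apart, with a median of 93.1% of the variance between groups. Most of the 87 lay in or beside the autosomal stretches higher in males described above, such as chr7:21243001-21981000, so that what they set apart there goes with sex. The log2 change there was -4.23 in obese control males and 0.94 in obese DDT males.

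The same libraries were also split in other ways, counted on every 10th window, with no allowance for the number of comparisons tried. In lean against normal atrazine males 1 of 100 splits, the real one, reached its 459 windows (highest other 241). In obese control males 1 of 100 reached 759 (349). Chance is argued against in each of these taken alone. In obese DDT males 1 of 100 reached 213, but the highest other gave 212. Not every split or window was tried, so chance cannot be excluded there. In obese control females 4 of 100 splits reached 1829 windows, so chance is excluded at 0.05 only if that comparison is taken alone. The highest other split there gave 15777. In lean control females 6 of 100 reached 1291 and the highest other gave 20009, so chance cannot be excluded. Splits that call several times the real count point to a structure among the control female pools other than phenotype. For atrazine females (0 real, highest other 15), control males (0, 30) and DDT females (0, 38), 100 of 100 splits gave as many, which a real count of 0 makes certain, so the splits decide nothing there. The 1 window called in DDT females was not among those sampled.

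Among the lineage comparisons, 1 of 100 splits reached the 9493 windows of atrazine against control males (highest other 2693). Chance is argued against there if that comparison is taken alone, which says nothing about a batch that goes with lineage. For atrazine against control females 3 of 100 reached 3045, but the highest other gave 7385, so chance is excluded only if that comparison is taken alone. For DDT against control females 5 of 100 reached 7236 (11187), so chance cannot be excluded. For the males of that comparison the real count was 0 (100 of 100, highest other 143), which decides nothing, as the 4 called windows were not among those sampled. For the differences between effects 40 splits were drawn. Atrazine against control leanness in males was reached by 1 of 40 splits (739 windows, highest other 7), the smallest share that 40 splits can give. Chance is argued against for this difference taken alone. Chance cannot be excluded for DDT against control obesity in males (7 of 40, 1 window, highest other 1097) or for the differences between the sexes in atrazine leanness (3 of 40, 217, 299) and DDT obesity (3 of 40, 33, 104). A real count of 0 again decides nothing for atrazine against control leanness in females (40 of 40, 0, 2593), DDT against control obesity in females (40 of 40, 0, 2444) and the differences between the sexes in control leanness (40 of 40, 0, 4041) and control obesity (40 of 40, 0, 5255). Where the highest other split lies far above the real count, a structure of the pools other than the groups is again present.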
